A study of Homo sapiens with 12 samples.

How the data were processed

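Poly(A) RNA of HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, was sequenced in 12 libraries. Per the labels, cells received 2 μM CP25, described there as a macrocyclic inhibitor of the decapping enzyme Dcp2, or vehicle, for 18 h. Actinomycin D, which blocks transcription, was then added at 5 μg/mL, and RNA was taken at 0 h and at 2 h. The labels put 3 libraries in each of the 4 groups (vehicle at 0 h, CP25 at 0 h, vehicle at 2 h, CP25 at 2 h). They number the replicates 1 to 3 and do not say whether these were separate cultures, so p-values measure the spread between these libraries, which may be technical.

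The deposited expression values are FPKM (fragments scaled to the length of the transcript and to the mapped fragments of the library), 1 column per library, in 1 table for 0 h and 1 for 2 h. Per the submitters' processing notes, CASAVA 1.8.2, Trimmomatic 0.36 and Bowtie2 2.2.3 were used with the hg19 build. The program that made the FPKM values and the annotation behind it are not given in the sources used here. The authors also deposited a comparison of CP25 with vehicle for each time, with a mean FPKM per group and a p-value. The group means lay within 1% of the mean of the 3 libraries for 100% of genes above 1 FPKM. That p-value was taken as unadjusted, since no adjusted column was present, and its own log2 ratio was not used because 1240 entries at 0 h and 1274 at 2 h could not be read as finite numbers. Both tables list the same 23615 gene symbols. A few symbols had been turned into dates and were kept in the fits without being named.

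No read counts were present. The depth was estimated from the step between the lowest FPKM values of genes of known length, which equals 1 fragment. It came to 14.4 to 24.3 × 10⁶ fragments per library at 0 h and 24.1 to 32.2 × 10⁶ at 2 h. At these depths, 1 FPKM of a transcript of 2 kb stands for 29 to 64 fragments. Transcript length and GC content came from GENCODE 29, which had a value for 21157 of the symbols (89.6%).

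From the deposited FPKM, log2(FPKM + 1) was computed here, and genes with a mean of at least 1 FPKM over the libraries in a fit were tested. CP25 was compared with vehicle within each table with limma 3.58.1 in R 4.3.3, using moderated variances with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. The difference of CP25 effects, 2 h minus 0 h, was the interaction contrast in a fit of all 12 libraries. Because it subtracts a ratio within 1 table from a ratio within the other, a scale factor per table cancels. Levels at 2 h against 0 h compare values from 2 tables that are taken as scaled separately, so they are described without a test. FPKM is a share of each library: where transcription was fully blocked, a value that rises over 2 h has fallen less than the average transcript. Whether the block was complete for every gene was not tested.

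Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 5 measured genes were tested against all other genes with camera from limma, at its preset inter-gene correlation of 0.01 and again with an estimated correlation. The score of a list in a library was the mean log2 value of its genes minus the mean of all tested genes, and scores were compared by exact two-sided permutation of the libraries within each time. With 3 libraries against 3 the smallest p is 0.1, and with the 400 labellings of both times it is 0.005. Intervals for a difference of effects on a score invert that permutation test, with the tested difference shared evenly between the times. Fast-falling genes were the 10% with the lowest mean of the vehicle and CP25 log2 ratios of 2 h to 0 h.

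Named genes were, per comparison, those past adjusted p 0.05 with full separation of the libraries (up to 10 per direction). Where fewer passed, those with the smallest p were added up to 5 per direction, given as values only. DCP2, its cofactors DCP1A, EDC4, DDX6, LSM1 and XRN1, the reported Dcp2 substrates EXOSC4 and IRF7, and MYC, FOS, JUN, IER2 and GAPDH were named throughout, as were 2 to 4 members of each list called or described. Small RNA genes and clone names were skipped unless nothing else passed. The genes named for the fall between 0 h and 2 h were chosen after their values were seen, as those with the largest changes and the extremes of each list.

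The numbering was checked for pairing through the correlation, across genes, of each library's deviation from its group mean. At 2 h, vehicle and CP25 libraries of the same number correlated at 0.35, 0.44 and 0.15, so the numbers pair the libraries by the rule set in advance (all 3 above 0.1). The pairing comes from the data, since the labels give only the number.

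The fits were tested on simulated values with the observed means and standard deviations, independent between genes and between libraries. In these, 200 genes were changed by known folds of FPKM + 1, which are larger folds of FPKM for genes near 1 FPKM. Spread shared by libraries of the same number was not simulated, so the shares and false calls do not cover it. At 0 h (12365 genes) limma recovered 70.1% of 1.5-fold, 86.6% of 2-fold and 98.5% of 4-fold changes with 7 false calls. At 2 h (11745 genes) the shares were 62.7%, 83.6% and 98.5% with 14 false calls. For the difference of effects (12183 genes) they were 46.3%, 91.0% and 98.5% with 10 false calls. Alternatives were a pseudocount of 0.1, no filter or a filter at 5 FPKM, median centring, quantile normalization, no variance trend, a replicate block, leaving out each library, the estimated correlation, another definition of the fast-falling genes and the authors' own test. Removal of small RNA genes, and of a smooth trend on transcript length and GC content in each library, were added after the data were seen. So were permutations in which treatments are swapped only between libraries of the same number, and the split of the intervals at a mean of 5 FPKM.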

Results

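The 12 libraries profiled poly(A) RNA of HEK293T cells after 18 h with CP25 or vehicle and either 0 h or 2 h of actinomycin D, with 3 libraries per group. The estimated depth was 14.4 to 24.3 × 10⁶ fragments per library at 0 h and 24.1 to 32.2 × 10⁶ at 2 h. Within a group, log2 values of 2 libraries correlated across genes at 0.971 to 0.988. Of the transcripts the study is about, DCP2, the catalytic subunit of the decapping complex, was expressed at 22.5 ± 0.465 FPKM in vehicle and 21.8 ± 0.321 FPKM in CP25 at 0 h (SD, n = 3). Markers of haematopoietic cells and of keratinised or glandular epithelium were not expressed at 1 FPKM in either table: the highest were CD68 at 0.749 FPKM and MUC1 at 0.906 FPKM at 0 h.

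The first question is which mRNAs declined relative to the average transcript during the block of transcription. By their values, short-lived regulatory mRNAs stood far below their 0 h level in both treatments, whereas the median transcript was nearly level. FPKM is a share of each library, so the median does not show how much mRNA was lost in total. Percentages left compare such shares. MYC, the growth-promoting transcription factor, went from 64.9 ± 10.8 FPKM to 9.83% of that level in vehicle and from 65.3 ± 12.3 FPKM to 10.0% in CP25 (SD, n = 3). JUN, a subunit of AP-1, was left at 10.0% and 9.11% in vehicle and CP25. NFKBIA, the inhibitor of NF-κB, was left at 6.51% and 4.64%, and BAMBI, a TGF-β pseudoreceptor, at 3.76% and 4.76%. ZNF703 and ZNF503, zinc-finger repressors, had the lowest mean of both log2 ratios among genes outside the small RNA and clone names. These ratios of FPKM + 1 were -3.34 and -3.30 in vehicle and -3.50 and -3.27 in CP25. By percent left, NFKBIA and BAMBI stood lower than ZNF703 (8.17% in vehicle, 7.2% in CP25) and ZNF503 (8.37% and 8.52%).

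As a group, 39 measured immediate-early and AU-rich mRNAs had a median log2 ratio of -1.69 in vehicle and -1.73 in CP25, against -0.18 and -0.16 for all 12183 genes. In vehicle 30 of the 39 had a log2 ratio below -1, and in CP25 31 did. IER2, an immediate-early gene, was left at 21% in vehicle and 21.8% in CP25, whereas BTG3 of the same list was left at 84.5% and 83.9%. FOS stayed below 1 FPKM on average. The distance of this list from all genes was -1.52 in vehicle. It came to -0.93 with no filter on low values and -1.87 with a pseudocount of 0.1, since the log2 ratio of a weakly expressed gene depends on the pseudocount.

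Zinc-finger genes formed the other group with a low median, -0.80 in vehicle and -0.74 in CP25 over 374 genes. Of these, 120 had a log2 ratio below -1 in vehicle and 114 in CP25. ZNF574 was left at 7.18% and 6.27%, and ZNF217 at 15.1% and 14.9%, while ZNF664 stood at 120% in both treatments. The p53 targets had a median of -0.37 in both treatments. Within that list PPM1D, a p53-induced phosphatase, was left at 23.1% in vehicle and 22.6% in CP25, and CCNG1 stood at 133% and 134%.

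mRNAs of the translation apparatus lay at the other end. Cytoplasmic ribosomal protein genes had a median log2 ratio of 0.35 in vehicle and 0.28 in CP25 (80 genes), and translation factors of the TOP class, whose mRNAs share a 5′ oligopyrimidine motif, 0.38 and 0.40 (20 genes). EEF1A1, the elongation factor, stood at 151% and 146%, and RPS24 at 154% and 166%. Hypoxia and glycolysis genes had medians of 0.22 and 0.16 (29 genes), with LDHA at 170% and 167% and GAPDH, the usual reference gene, at 121% and 118%. Heat-shock genes were split: HSPD1 stood at 150% and 144%, and DNAJB1 was left at 25.2% and 23.5%. Among the largest rises were MTRNR2L8, at 433% in vehicle and 488% in CP25, MTRNR2L2, at 308% and 450%, and HIST1H4C, at 357% and 392%. Whether slower decay alone gives rises of this size was not tested.

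The mRNA decay machinery itself was mixed. DCP2 stood at 97.6% in vehicle and 99.1% in CP25, and LSM1 at 107% and 105%. DCP1A was left at 48.3% and 52.3%, and PNRC1, a decapping coactivator, at 23.0% and 22.7%. In the deadenylation and exosome list TOB1, which recruits deadenylases, was left at 20.6% and 22.0%, and PABPC1 stood at 129% and 139%. EXOSC4, a reported Dcp2 substrate, was left at 44.2% in vehicle and 39.0% in CP25. Targets of nonsense-mediated decay had medians of -0.18 and -0.17, close to all genes.

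**Figure D1:**
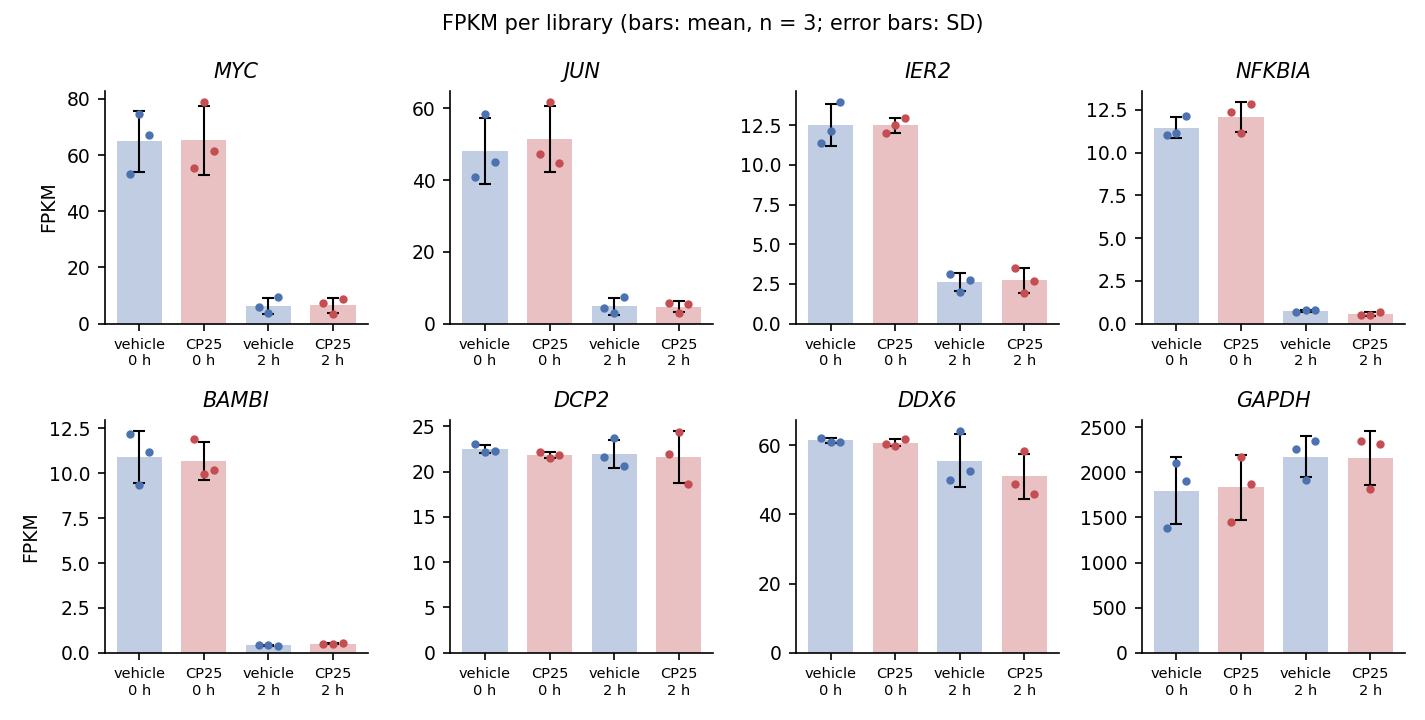
FPKM of 8 genes in each library, by treatment and time after actinomycin D (bars, mean of 3 libraries; error bars, SD; points, libraries). MYC, JUN, IER2, NFKBIA and BAMBI are low at 2 h in both treatments, and DCP2 stays near 22 FPKM.

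The profiles of both treatments were alike, less so with small RNA genes included. Over all 12183 genes the ratios in vehicle and CP25 had a Pearson correlation of 0.857, and their difference had an SD of 0.27 on the log2 scale. Of 12021 genes outside the small RNA class, 822 had a log2 ratio below -1 in vehicle and 819 in CP25, and 729 did in both. Across these genes the Pearson correlation was 0.967 (genes are not independent replicates), and their difference had an SD of 0.12. No test was made of the fall itself, because the times were deposited in separate tables.

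**Figure D2:**
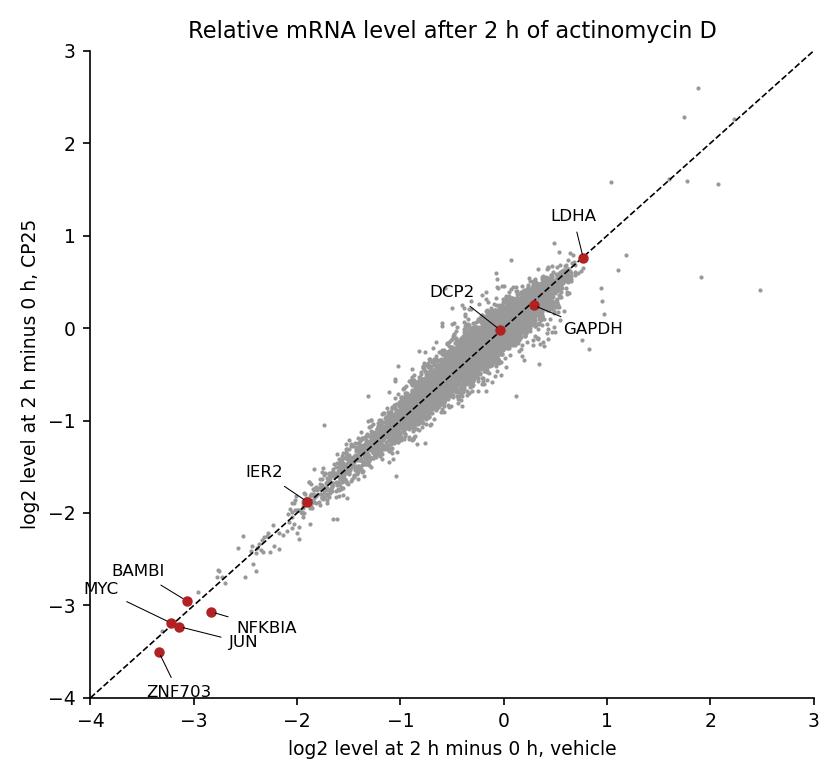
The log2 level at 2 h minus 0 h in vehicle (x axis) and CP25 (y axis), 1 point per gene outside the small RNA class, from means of 3 libraries per group. Genes with deep falls such as MYC and JUN and genes with raised shares such as LDHA lie along the line of equal change.

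**Figure D3:**
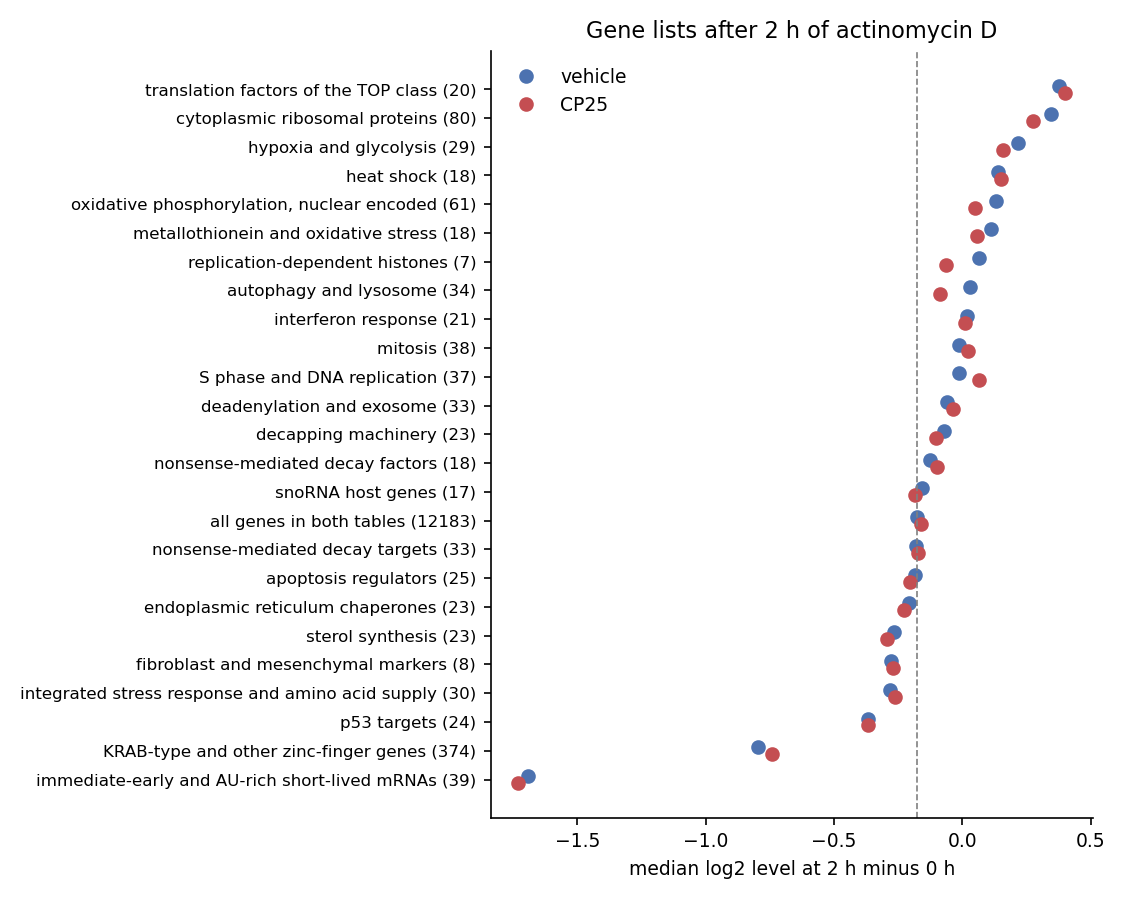
Median log2 level at 2 h minus 0 h of each gene list, with the number of measured genes, in vehicle and CP25. The dashed line marks the median of all genes in vehicle, and immediate-early and zinc-finger genes lie lowest in both treatments.

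The comparison at 0 h asks what 18 h of CP25 did to steady-state mRNA levels. No gene passed the test: of 12365 genes, limma called 0 at adjusted p 0.05, with 43 higher and 45 lower in CP25 at unadjusted p under 0.05, where chance alone would give 618. That expectation holds only where libraries share no spread by number. At 2 h these do, and at 0 h they do for some genes, such as the hypoxia and glycolysis list. Its score was 1.48, 2.02 and 1.74 in vehicle replicates 1 to 3 and 1.55, 2.13 and 1.67 in the CP25 replicates. With the numbers as a block, limma reached unadjusted p under 0.05 for 857 genes, above the 618, and called 0. The authors' own p-values, adjusted here, also called 0. DCP2 had a CP25 to vehicle ratio of 0.97 (95% interval on the log2 scale -0.16 to 0.07). MYC had a log2 change of 0.01 (-0.38 to 0.39), EXOSC4 0.06 (-0.34 to 0.46) and GAPDH 0.03 (-0.50 to 0.56). IRF7, the other reported Dcp2 substrate, had deposited means of 0.00934 FPKM in vehicle and 0.0249 FPKM in CP25 and was not tested.

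The genes with the smallest p had small differences. Higher in CP25 by value were FKBP2 (log2 change 0.19, limma adjusted p = 1), LENG1 (0.25), NR2C2AP (0.25), SLC35G2 (0.19) and MPZL3 (0.33). Lower by value were UFSP1 (-0.36), the ribosomal protein pseudogene RPS26P11 (-0.34), TEFM (-0.18), TUBG2 (-0.25) and ZNF577 (-0.45). FKBP2, an endoplasmic reticulum prolyl isomerase, measured 38.0 ± 0.617 FPKM in vehicle and 43.4 ± 1.02 FPKM in CP25 (SD, n = 3). TEFM, the mitochondrial transcription elongation factor, measured 13.9 ± 0.356 and 12.1 ± 0.0361 FPKM. Values of RPS26P11 are uncertain because reads can be shared with its parent gene. Among DCP2 cofactors the log2 changes were -0.13 for DCP1A, -0.02 for EDC4, -0.02 for DDX6, -0.02 for LSM1 and -0.10 for XRN1, and the immediate-early genes JUN and IER2 had 0.10 and 0.00185, all with adjusted p = 1.

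Several gene groups shifted by a few percent at 0 h under camera's preset correlation. Nuclear-encoded oxidative phosphorylation genes were higher in CP25, with 57 of 61 positive and a median log2 change of 0.05 (camera adjusted p = 1.79e-06). Sterol synthesis genes (median 0.06, 18 of 23 positive, adjusted p = 0.00242), p53 targets (0.06, 16 of 25, adjusted p = 0.00486), autophagy and lysosome genes (0.03, 28 of 34, adjusted p = 0.00638) and cytoplasmic ribosomal protein genes (0.03, 67 of 80, adjusted p = 0.0325) were also higher. Zinc-finger genes were lower, with 276 of 393 negative and a median of -0.04 (adjusted p = 0.000458). None of the 6 calls held with an estimated correlation, where the smallest adjusted p of the 24 lists tested was 0.931, and 0 members of any list passed, both over all genes and adjusted over the list alone. The ribosomal call was also lost with no filter, with libraries centred on the median or quantile normalized, and with the length and GC trend removed, which also ended the autophagy and lysosome call.

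Examples, none past the test, were NDUFC1 (log2 change 0.19) and NDUFA3 (0.13), subunits of respiratory complex I, the sterol enzymes MSMO1 (0.10) and PMVK (0.14), and the p53 targets FAS (0.17) and AEN (0.16). Others were HEXA (0.12) and ATP6V1H (0.11) of the lysosome, RPS27L (0.13) and RPL37 (0.13), and ZNF177 (-0.36) and ZNF724P (-0.40). The 18 lists not called included decapping machinery (median -0.01, camera adjusted p = 0.95), immediate-early and AU-rich mRNAs (0.00358, 0.439) and targets of nonsense-mediated decay (-0.02, 0.439). Without vehicle replicate 1 at 0 h, no list was called. Without CP25 replicate 2 only the sterol and autophagy calls of the 6 were left, and without CP25 replicate 3 only those of p53 targets and zinc-finger genes, so the oxidative phosphorylation call was lost without each of these 3 libraries. The p53 call was lost without vehicle replicate 3 and the autophagy call without CP25 replicate 1. Leaving out any 1 of the 6 libraries gave 1 to 4 genes, all of them small RNA genes.

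After 2 h of transcription block, the comparison asks whether transcripts that survived differed between CP25 and vehicle. Of 11745 genes, limma called 1, the box C/D small nucleolar RNA gene SNORD76. It measured 81.7 ± 48.3 FPKM in vehicle (SD, n = 3) and was listed at 0 in all 3 CP25 libraries (limma adjusted p = 0.00155), so no fold is given. At 0 h the same gene was listed at 0 in 2 of 3 vehicle libraries. At unadjusted p under 0.05 there were 45 genes higher and 42 lower against 587 expected by chance, and the other 3 splits of the libraries that part all pairs gave 35 to 81 genes. With the pairs as a block limma reached that p for 814 genes, above the 587, and called 1 gene. The authors' p-values, adjusted here, called 0.

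No mRNA passed. MYC had a log2 change of 0.03 (95% interval -0.77 to 0.83), JUN 0.01 (-0.72 to 0.73), IER2 0.02 (-0.40 to 0.45), EXOSC4 -0.14 (-0.49 to 0.22) and DCP2 -0.03 (-0.28 to 0.22). The intervals are from the fit without the block, which counts spread shared by libraries of the same number as error. The cofactors DCP1A, EDC4, DDX6, LSM1 and XRN1 had -0.02, -0.06, -0.12, -0.04 and 0.14, and GAPDH -0.01, all with limma adjusted p = 1. Higher by value with the smallest p were KIAA1919 (0.35), SAMD5 (0.33), the recombination gene XRCC2 (0.27), LMBRD2 (0.26) and ARHGAP11B (0.25). Lower by value were BEX5 (-0.39), the read-through locus TGIF2-C20orf24 (-0.38), the metallothioneins MT1X (-0.49) and MT2A (-0.32), and DDT (-0.24). MT1X measured 14.9 ± 1.92 FPKM in vehicle and 10.3 ± 1.83 FPKM in CP25, and MT2A 21.3 ± 1.36 and 16.9 ± 1.56 FPKM (SD, n = 3). ARHGAP11B is a partial copy of ARHGAP11A, and reads of metallothionein paralogs can also be shared, so the split between such genes is uncertain.

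Of 24 gene lists, 1 was called at 2 h: oxidative phosphorylation genes were lower in CP25, with 44 of 61 negative and a median log2 change of -0.02 (camera adjusted p = 0.00205). The call did not hold with an estimated correlation, where the adjusted p was 0.966. UQCRQ (-0.18), COX8A (-0.20), ATP5G3 (-0.13) and ATP5A1 (-0.09) had the smallest p in that direction, and 0 members passed over all genes or adjusted over the list alone. Immediate-early and AU-rich mRNAs had a median of 0.00556 (28 genes, camera adjusted p = 0.779) and targets of nonsense-mediated decay -0.04 (32 genes, adjusted p = 0.281). Leaving out single libraries called 1 to 7 lists. The oxidative phosphorylation list was not among them without vehicle replicate 1 or without CP25 replicate 2 at 2 h.

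The comparison closest to the study's title is the difference of CP25 effects, 2 h minus 0 h. It measures whether CP25 changed how far an mRNA declined relative to the average transcript of its library. FPKM is a share of each library, so a change in decay common to all mRNAs would not show. The libraries hold poly(A) RNA, so a change confined to transcripts that had lost their poly(A) tail would not show either. No gene passed: of 12183 genes limma called 0, with 94 above and 59 below zero at unadjusted p under 0.05 against 609 expected by chance. On the scale of FPKM + 1, which understates folds of genes near 1 FPKM, the interval of the difference excluded a 2-fold change for 97.6% of genes and a 1.5-fold change for 86.7% (95% limma intervals, not adjusted for the number of genes). With a pseudocount of 0.1 the shares were 94.1% and 74.6%: 98.1% and 89.1% of the 8865 genes with a mean of at least 5 FPKM, and 83.5% and 35.7% of the 3318 below. MYC had a difference of 0.03 (-0.90 to 0.95), JUN -0.09 (-0.94 to 0.76), IER2 0.02 (-0.44 to 0.49) and EXOSC4 -0.20 (-0.74 to 0.34), on the log2 scale. For MYC and JUN the interval therefore still allowed changes of up to 1.93-fold and 1.69-fold in favour of CP25, and of up to 2.07-fold and 1.84-fold with a pseudocount of 0.1. These intervals come from the fit without the replicate block, which counts spread shared by libraries of the same number as error. With the block the limma p of the difference was 0.832 for MYC, against 0.953 without it. For JUN it was 0.603 against 0.821, so part of the width is such spread.

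Above zero by value with the smallest p were SAMD5 (0.48, 95% interval 0.23 to 0.73), RPS26P11 (0.67), XPNPEP3 (0.56), the aryl hydrocarbon receptor AHR (0.48) and SPATA5 (0.43). Below zero were NR2C2AP (-0.44), C9orf89 (-0.51), ICAM3 (-0.38), ITGAE (-0.34) and MAP1LC3B2 (-0.58). All 10 had limma adjusted p = 1. XRN1, the 5′ to 3′ exonuclease that degrades decapped RNA, had 0.24 (95% interval 0.00835 to 0.48, adjusted p = 1). DCP2, DCP1A, EDC4, DDX6 and LSM1 had 0.02, 0.11, -0.04, -0.10 and -0.03, and GAPDH -0.04.

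Fast-falling mRNAs did not separate from the rest. The class held 1219 genes, with a median log2 ratio of 2 h to 0 h of -1.15 in both treatments. The median difference of effects in this class lay -0.0103 from that of all genes (camera from limma, p = 0.303 for this single class, and 0.743 with an estimated correlation). Its score per library gave a difference of -0.0148 (95% permutation interval -0.128 to 0.106, exact permutation p = 0.78), a 0.99-fold change with an interval of 0.915 to 1.08. The immediate-early and AU-rich list gave -0.0265 (-0.287 to 0.235, permutation p = 0.805), and targets of nonsense-mediated decay gave -0.0284 (-0.122 to 0.067, permutation p = 0.515). The value without 1 library ranged from -0.0402 to 0.0193, and camera's p was 0.0242 without vehicle replicate 1 at 0 h, 0.000763 without CP25 replicate 2 at 0 h, 0.00461 without vehicle replicate 1 at 2 h and 0.00919 without CP25 replicate 3 at 2 h.

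**Figure D4:**
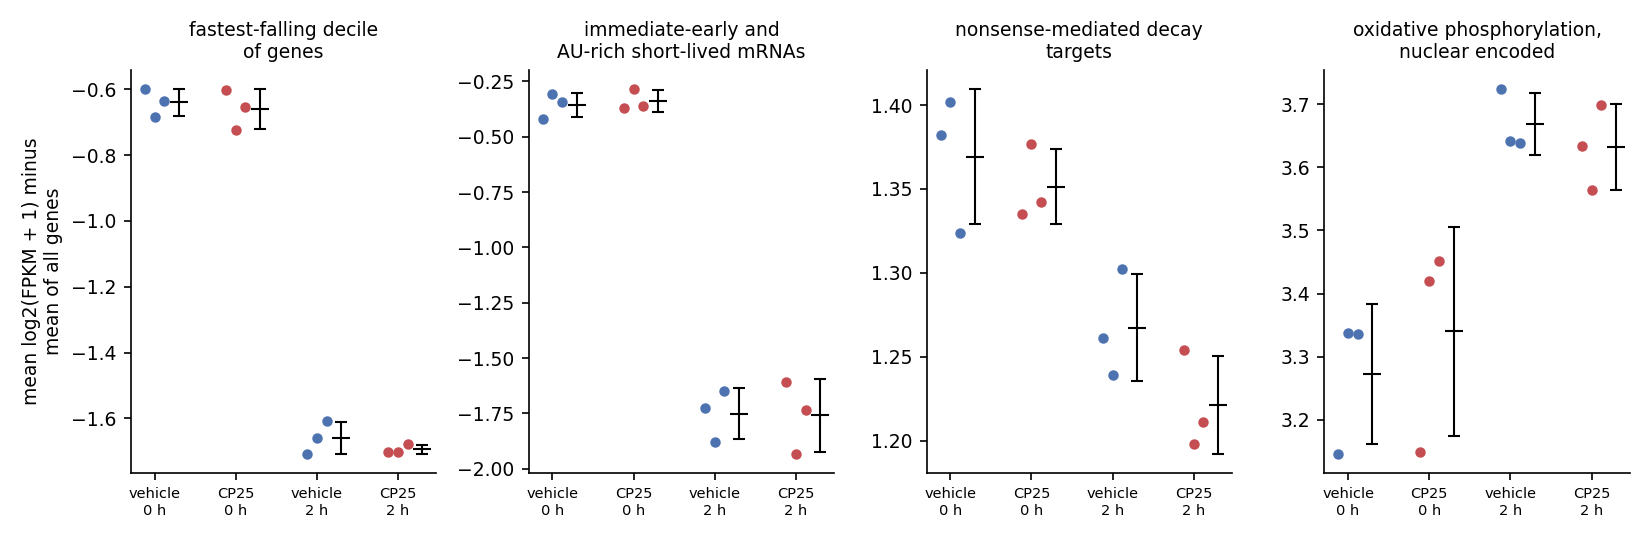
Score per library of 4 gene sets, the mean log2(FPKM + 1) of the set minus that of all tested genes (points, libraries; black, mean and SD of 3). Within each time the vehicle and CP25 libraries overlap in all 4 sets.

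Under the preset correlation 5 lists differed in their CP25 effect between the times. Oxidative phosphorylation genes had a median difference of -0.09 with 55 of 61 negative (camera adjusted p = 7.96e-08), sterol synthesis genes -0.06 with 19 of 23 negative (adjusted p = 0.00834), ribosomal protein genes -0.04 with 59 of 80 negative (0.00834) and autophagy and lysosome genes -0.03 with 29 of 34 negative (0.00834). Zinc-finger genes had 0.05 with 237 of 374 positive (adjusted p = 0.0196). These lists were all called at 0 h with the other sign, and only oxidative phosphorylation genes were called at 2 h. The median effects at 2 h were -0.00496 for sterol synthesis, -0.0102 for ribosomal protein, 0.00927 for zinc-finger and -0.00614 for autophagy and lysosome genes. By median, the differences of these lists thus come mainly from 0 h. The p53 targets, at -0.07 with 16 of 24 negative, were not called (adjusted p = 0.0517). With an estimated correlation none held, and the smallest adjusted p of the 24 lists was 0.965. UQCRQ (-0.30), NDUFC1 (-0.28), PMVK (-0.27), RPS29 (-0.38), HEXA (-0.19) and ZNF708 (0.50) were among the members with the smallest p, and 0 members passed over all genes or adjusted over the list alone. Exact permutation of the libraries gave p = 0.365 for the oxidative phosphorylation score (difference -0.104, interval -0.368 to 0.179), and adjusted over the 11 scores tested the p was 0.895. With treatments at 2 h swapped only between libraries of the same number, which pair there, the permutation p was 0.362 over 160 labellings. Such swaps gave a permutation p of 0.15 for sterol synthesis and 0.05 for autophagy and lysosome genes, and the smallest adjusted p of the 11 scores was 0.55. By the rule set in advance the numbers were not taken as pairs at 0 h, although some genes share spread by number there. Swapped within numbers at both times, sterol synthesis reached the smallest possible permutation p of 0.0312 (0.258 when adjusted over the 11). The oxidative phosphorylation call for the difference was lost without vehicle replicate 1 at 0 h and held without each of the other 11 libraries. Without vehicle replicate 1 at 0 h, the library with the lowest estimated depth, 0 lists were called, and without vehicle replicate 2 at 2 h 12 were. Leaving out vehicle replicate 2 or CP25 replicate 1 at 0 h called 8 lists each, CP25 replicate 3 at 0 h 3, and vehicle replicate 1 or CP25 replicate 2 at 2 h 2 each.

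CP25 effects at the 2 times did not go together across genes. Over 12183 genes the Pearson correlation was -0.09 and Spearman's rho -0.17. The Pearson value was -0.171 without small RNA genes and -0.0431 with the length and GC trend removed. Genes are not independent replicates, and 25 of 100 splits of the libraries gave a Pearson value as far from 0. Without CP25 replicate 2 at 2 h Spearman's rho was 0.0132, of the other sign, and without CP25 replicate 3 at 2 h it was -0.273. Without vehicle replicate 1 at 0 h the Pearson value was -0.0232.

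The authors' deposited comparison listed 117 genes below p 0.05 at 0 h, 17 higher and 100 lower in CP25, and 74 at 2 h, 45 higher and 29 lower. It tested 13306 and 13275 genes, of which chance alone would give 665 and 664. All these counts, like those of limma without the block, lie below what chance would give. By the deposited values at 2 h, SLC39A10, a zinc importer, measured 29.3 FPKM in vehicle and 38.0 FPKM in CP25, and TFRC, the transferrin receptor, 79.7 and 99.7 FPKM. These 2 were chosen after their values were seen. In replicates 1 to 3 at 2 h, TFRC measured 74.3, 59.7 and 105 FPKM in vehicle and 76.2, 127 and 95.5 FPKM in CP25. Its higher mean in CP25 thus lay in replicate 2, and replicate 3 went the other way. Between the deposited lists and those of limma below p 0.05, 13 genes were shared at 0 h and 31 at 2 h, where independent lists would share 0.629 and 0.379. Both methods read the same libraries, so the overlap is no independent evidence.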

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

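The permutation tests of the oxidative phosphorylation score, its length and GC check as a single list and the swaps within numbers for all 11 scores were chosen after the results were seen. For 5 gene lists the CP25 effect at 2 h differed from that at 0 h by the interaction test under camera's preset correlation. The median differences were -0.0587 for sterol synthesis, -0.0927 for oxidative phosphorylation, -0.0372 for cytoplasmic ribosomal proteins, 0.0474 for zinc-finger genes and -0.0295 for autophagy and lysosome genes, all below 0.1 on the log2 scale. No call held with an estimated correlation.

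Spread between libraries and an effect of CP25 both stay open. Exact permutation of the libraries gave p = 0.365 for the oxidative phosphorylation score, so a spread that the genes of a list share may account for the call. That test counts spread common to libraries of the same number as error. With treatments swapped only within numbers at 2 h, where these pair the libraries, the permutation p was 0.362, and with swaps within numbers at both times it was 0.0938, where 0.0312 is the smallest possible. By number, CP25 minus vehicle was 0.00394, 0.0829 and 0.115 at 0 h and -0.0913, -0.0781 and 0.0602 at 2 h. For sterol synthesis it was 0.0937, 0.000747 and 0.0684 at 0 h and -0.00902, -0.0199 and -0.0468 at 2 h, higher at 0 h and lower at 2 h in all 3 numbers. Its permutation p was 0.15 with swaps at 2 h and 0.0312 with swaps at both times, and autophagy and lysosome genes had 0.05 and 0.0625. Adjusted over the 11 scores the smallest p was 0.55 and 0.258, so no score passed, and 3 libraries per group leave effects of this size open. Of 100 splits of the libraries within times, 76 gave at least the 5 lists of the real split, and the highest of the others gave 14, so chance cannot be excluded. CP25 effects followed transcript length (Spearman -0.33 at 0 h and 0.13 at 2 h across genes) and GC content (0.13 and -0.43). After a smooth trend on both was removed from each library, 1 of the 5 lists stayed past adjusted p 0.05. That met the outcome set before this test for a length and GC bias, at most 1 list. Ribosomal protein genes moved from a median of -0.0372 to -0.00723 (adjusted p = 0.197). The other calls ended with most of the median kept: sterol genes went from -0.0587 to -0.0589 (0.0651), zinc-finger genes from 0.0474 to 0.0324 (0.194) and autophagy genes from -0.0295 to -0.0189 (0.0674). The outcome set beforehand counts only calls, and these 3 were lost with most of the median kept. It therefore cannot decide for or against a length and GC bias, which stays open for the lists as a set. Oxidative phosphorylation genes went from a median of -0.0927 to -0.0522 (adjusted p = 3.01e-06). Their mean score kept more, from -0.104 to -0.0795 (exact permutation p = 0.3), and for them a length and GC bias and a CP25 effect cannot be told apart, because 3 libraries per group leave the interval wide.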

How the results depend on the processing

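The removal of small RNA genes and of the length and GC trend were chosen after the data were seen. Counts of called genes at 0 h and for the difference of effects stayed at 0 under every setting except the leaving out of single libraries, which gave 1 to 4 genes at 0 h and 0 to 3 for the difference. At 2 h the single call, SNORD76, remained under each other planned setting of the limma fit. Without small RNA genes, with the length and GC trend removed (SNORD76 has no length there) and with the authors' own test, 0 genes were called at 2 h, and leaving out single libraries gave 1 to 7. All calls added by leaving out a library were small RNA genes.

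With the replicate block, 0 genes were called at 0 h, 1 at 2 h and 0 for the difference of effects, and 8, 1 and 6 lists. Unadjusted p under 0.05 was reached by 857, 814 and 1284 genes with the block against 88, 87 and 153 without it. At 2 h, where the numbers pair the libraries, all 3 pairs correlated best with their own number. At 0 h the same check gave 0.26, -0.01 and 0.12, so by the rule set in advance the numbers were not taken as pairs there. Vehicle replicate 2 correlated best with another number (0.068). Swapping treatments within numbers at 0 h gave 384 to 475 genes with the block, against 857 for the real labels. At unadjusted p under 0.05 without the block, the 3 other splits at 0 h that part all numbers gave 66 to 99 genes. The remaining 6 gave 266 to 2356. This hint from the data points to spread shared by number at 0 h too, for some genes. Among the lists the block added hypoxia and glycolysis (adjusted p = 0.00506) and TOP-class translation factors (0.0343) at 0 h and p53 targets (0.00625) for the difference, none of them past 0.05 with an estimated correlation as well. It changed no other call.

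With an estimated correlation 0 lists were called at 0 h, at 2 h and for the difference. For the difference, no filter on low values left 1 list and removal of the length and GC trend 2. The p53 targets (median -0.0746, adjusted p = 0.0517) were called for the difference in that setting and also with quantile normalization and without small RNA genes, which gave 6 lists each. Quantile normalization gave 2 lists at 2 h. Leaving out single libraries gave 0 to 9 lists at 0 h, 1 to 7 at 2 h and 0 to 12 for the difference. The 0 at 0 h and for the difference came without vehicle replicate 1 at 0 h, the library with the lowest estimated depth. The cause was not tested.

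The fast-falling class kept its side of the threshold in all tested settings with all libraries (-0.0135 to -0.00208), and ranged from -0.0402 to 0.0193 without single libraries. Setting the class from 1 vehicle library per time gave a mean of -0.0223 over 9 choices, with a range of -0.0659 to 0.0404 and no test. The correlation of effects was -0.171 (without small RNA genes) to -0.0431 with all libraries and -0.112 to -0.0232 without single ones, where Spearman's rho ranged from -0.273 to 0.0132. The immediate-early list lay -1.87 from all genes with a pseudocount of 0.1, -0.926 with no filter and -1.73 at 5 FPKM, against -1.52; the gene numbers (67 and 23 against 39) and the pseudocount differ by construction. All 1856 values of named genes kept their side of the threshold, and 77 not called changed sign. Of 1852 levels of named genes at 2 h against 0 h, 101 moved by more than 1 SD and 2 changed sign. Depth limits low genes: 1 FPKM of a 2-kb transcript stood for 29 fragments in the shallowest library.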

Other observations

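The test of small RNA genes, the count of splits for the 0 h and difference-of-effects gene counts, and the permutations and splits by replicate number were chosen after the results were seen. The score of the hypoxia and glycolysis list varied between libraries more than between treatments, and vehicle and CP25 libraries of the same number had like scores. DDIT4, a stress-induced inhibitor of mTORC1 from the integrated stress response list, showed the same order of libraries and measured 9.05, 39.5 and 14 FPKM in vehicle replicates 1, 2 and 3 at 0 h, and 10.9, 49.7 and 12 FPKM in the CP25 replicates. At 2 h replicate 2 was the lowest instead, with 1.20 FPKM in vehicle and 0.632 FPKM in CP25, against 6.88 to 11.4 and 5.96 to 8.44 FPKM in the others. PDK1 of the hypoxia list, which limits pyruvate oxidation, also had replicate 2 highest at 0 h, with 15.3 and 16.5 FPKM in replicate 2 at 0 h against 7.15 to 10.0 and 7.60 to 9.09 FPKM in the others. The score of the 29 genes was 2.02 and 2.13 in replicate 2 at 0 h against 1.48 to 1.74 in the other 4 libraries, and 1.79 and 1.76 at 2 h against 2.31 to 2.45. The CP25 effect on that score was 0.0357 at 0 h (exact permutation p = 0.8) and 0.00523 at 2 h (exact permutation p = 1). These genes were chosen after their values were seen.

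Such shared spread also shows in the splits of the libraries. At unadjusted p under 0.05 the real split gave 88 genes at 0 h and 87 at 2 h, and the highest of the other 9 splits gave 2356 and 2151, which points to a structure of the libraries other than treatment. At 2 h, where the numbers pair the libraries, the 3 other splits that part all pairs gave 35 to 81 genes and 3 to 5 lists, against 87 genes and 1 list for the real split, and the 6 splits that part 1 pair gave 148 to 2151 genes. At adjusted p 0.05, 6 of 10 splits gave at least the 1 gene of the real one at 2 h (highest other 4). At 0 h and for the difference of effects the real count was 0, which all 10 and all 100 splits reach by definition (highest other 3 in both), so these counts decide nothing. For lists, 7 of 10 splits gave at least 6 at 0 h (highest other 11) and 10 of 10 at least 1 at 2 h (highest other 12). With 10 splits no share under 0.05 can be reached. For the correlation of effects 25 of 100 splits lay as far from 0 as -0.0889 (farthest other 0.193), so chance cannot be excluded. After the length and GC trend was removed that correlation was -0.0431. With the replicate block at 2 h, 814 genes reached unadjusted p under 0.05, and the highest of the other 3 ways to swap treatments within pairs gave 665. That made 1 of 4 labellings as high, too few for a share under 0.05.

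SNORD76 stands for a class that poly(A) libraries measure poorly. At 2 h, 19 of 30 small RNA genes with a mean of at least 10 FPKM were listed at 0 in at least 1 library, against 0 of 6061 other genes. In 6 of the 19 other splits of the libraries, 10 at 0 h and 9 at 2 h, a small RNA gene was at 0 throughout one arm and above 10 FPKM throughout the other. FPKM estimates of small RNA genes that fall to 0 in some libraries may therefore account for the call, and it cannot be read as a change in SNORD76 itself.

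A hypothesis came from 3 genes noticed in the gene tables. The metallothioneins MT1X and MT2A had lower means, and the zinc importer SLC39A10 a higher mean, in CP25 at both times. On the log2 scale MT1X had -0.490 at 0 h and -0.495 at 2 h, MT2A -0.26 and -0.32, and SLC39A10 0.23 and 0.35. At 0 h MT1X measured 16.82, 19.97 and 29.45 FPKM in vehicle replicates 1 to 3. The CP25 replicates had 18.35, 11.94 and 15.42 FPKM, so replicate 1 went the other way. Of 6 pairs of the same number, 5 had the same sign for MT1X, and 6 for MT2A and SLC39A10. Lower zinc availability lowers metallothionein mRNA and raises that of SLC39A10, so a lower zinc supply in the CP25 cultures is a candidate explanation. It predicts lower mRNA of other zinc-induced genes whose values had not been looked at, of which SLC30A1, the zinc exporter, and MT1F were measured. Their mean CP25 effect over both times was -0.246 (95% permutation interval -0.433 to -0.0571, exact two-sided permutation p = 0.02 over 400 labellings). Both genes were measured in the libraries that gave the hypothesis. A chance spread between libraries shared by zinc-induced genes would carry over to them, so this p is not independent of how the hypothesis arose. The permutation treats the 2 times as independent. The labels do not say whether libraries of both times came from the same cultures, and if they did, this p may be too small. With treatments swapped only within numbers at 2 h the permutation p was 0.0375, and with swaps within numbers at both times it was 0.0625, where 0.0312 is the smallest possible.

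Without 1 library the mean ranged from -0.295 to -0.195, and the permutation p reached 0.05 without vehicle replicate 1 or CP25 replicate 2 at 0 h. A length and GC bias is argued against: with that trend removed the mean was -0.26 (interval -0.454 to -0.0724, permutation p = 0.015). Reads shared between metallothionein paralogs could make MT1F follow MT1X, and alone SLC30A1 had a mean effect of -0.17 (permutation p = 0.15). MT1F alone had -0.325 (permutation p = 0.13), so neither gene passed 0.05 by itself. MT1F also lay near the filter of 1 FPKM. At 0 h it measured 1.59 ± 0.516 FPKM in vehicle and 1.03 ± 0.492 FPKM in CP25 (SD). At 2 h the values were 1.77 ± 0.846 and 1.22 ± 0.413 FPKM. The measured genes may reflect zinc supply, but the mean rests on 2 genes and on the libraries that gave the hypothesis. Whether CP25 or a component of the preparations binds zinc was not tested. None of these genes passed limma's adjusted threshold, and SLC39A6, a related importer, had a mean effect of 0.0011. Zinc was the only hypothesis of this kind tested. A higher mean of TFRC in CP25 at 2 h, which lay in replicate 2, was noted too. The mean effect of TFRC over both times was 0.20 (permutation p = 0.245).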
